A study of Trichoderma atroviride with 24 samples.

How the data were processed

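Small RNA libraries had been made from total RNA of frozen Trichoderma atroviride mycelium with an Illumina TruSeq small RNA kit, per the labels' protocols. The fungus had been grown on potato dextrose agar in the dark. The labels give 24 libraries in 8 groups of 3, made of 2 strains (the wild type and a dcr2 mutant) and 4 culture conditions (growing alone, or facing Alternaria alternata before contact, at contact and after contact). Each strain has 1 group growing alone for all 3 stages. A difference between a stage and growing alone therefore cannot be told apart from culture age, and the stage comparisons of a strain share their controls. The labels number the replicates 1 to 3 within each group and do not say whether they came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

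The authors deposited 1 table of estimated counts per gene ID for all 24 libraries, not normalised. The unit was taken from the values: 11743 of the 11863 gene IDs held whole counts in every library, 120 IDs held at least 1 count that was not whole, and the totals differed between libraries. Bowtie, edgeR and limma are named in the submitters' processing notes without version or role. The genome build, the counting tool, the read length limits and whether strand was used are not given in the sources used here. The counts therefore do not separate sense from antisense reads, and genes that overlap or share near-identical sequence are uncertain. They also do not separate reads of the 2 fungi in the co-culture libraries, should reads of A. alternata align to T. atroviride genes.

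Gene IDs were used as the table gives them. The RefSeq gene list of T. atroviride P1 (assembly ASM2064779v1) was matched through its older locus tags, and 10686 IDs matched. That list gives locus tags and no gene names, so it served only to print locus tags and to order genes. Its chromosomes and start positions gave the order of protein-coding genes, in which distances to chromosome ends were counted in genes. The gene lists fixed before the data were examined (among them RNA interference genes) work on names or product descriptions, so none could be applied, and shares of reads by class or length were not analysed here. Counts at the dcr2 gene itself were not analysed here either, so no count at the targeted gene checks the strain labels.

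Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes passed the filterByExpr filter (8980 genes), library sizes were scaled by the trimmed mean of M values (TMM, factors 0.383 to 2.48), and quasi-likelihood models with robust dispersion estimates were fitted to all 24 libraries with 1 mean per group. Each comparison was a contrast of group means, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The difference between strains in their response (each co-culture stage against growing alone) was tested jointly over the 3 stages. Fold changes are log2 values, with a standard error equal to the absolute log2 fold change divided by the square root of the F statistic. CPM values (counts per 1e6) are TMM-scaled, and shares of counts are percentages of the library total without scaling.

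The rule for named genes was fixed before the data were examined. It took, per comparison, the genes with the smallest p among those past the threshold whose 3 libraries of one group all lay on one side of the 3 of the other. Because the IDs carry no names, at most 2 higher and 2 lower were taken. Where fewer than 3 genes passed, the 3 with the smallest p were named. Genes 297535, 300945, 300960, 298021 and 9789 were named after their values were seen, 298021 for the largest share of counts and the others for the largest differences in share among the genes called growing alone (3 lower, 1 higher). The log10 library totals of the strains were compared by an exact two-sided permutation test, within each condition and stratified over conditions.

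Replicates were compared with chi-square tests of their counts over genes with at least 20 counts in the pair. Every pair of replicates differed by more than counting noise, the closest pair being dcr2 before contact 1 and 3 with a chi-square of 1.46 per gene, so no library was treated as a second deposit of another. All pairs of dcr2 before contact lay at 1.46 to 1.79 per gene and the wild type before contact 1 and 3 at 1.91. Every other pair of replicates lay at 2.65 or more. Separate preparations of the same RNA would also differ by more than counting noise, and this test does not exclude them. The spread of dcr2 before contact in particular may therefore be technical, and its SDs and p-values need not reflect separate cultures. Same-numbered libraries were checked for pairing by correlating their deviations from the group means. All 3 correlations were above 0.1 for the wild type before contact against alone (0.11, 0.32 and 0.15) and for dcr2 after contact against alone (0.63, 0.75 and 0.91), and not in the other 8 comparisons. In dcr2 the third libraries of both groups share a profile unlike the others, as described below. That shifts both group means alike and raises these correlations, so they do not show pairing by number. There 2 of the libraries correlated best with their own number.

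Alternatives chosen before the data were examined were RLE size factors, library totals without TMM factors, no filter, a filter on 10 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a fit to the compared groups alone, the replicate number as a block, and each library left out in turn. After the data were seen, 2 libraries stood apart from the other 22 (the third of dcr2 growing alone and the third of dcr2 after contact), and a fit without them was added. The common biological coefficient of variation was 0.591 with 24 libraries and 0.298 with 22, and the latter fit tested 8337 genes. A fit to 21 libraries, also without the second library of dcr2 at contact, was added for the contact comparison.

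The test was run on simulated counts with known changes, drawn from each gene's mean over all libraries and the real library sizes. Noise was independent between libraries. The simulation holds no other group differences and no profile shared by the 2 libraries that stood apart, so its false calls need not hold for the real counts. For dcr2 against wild type growing alone with 24 libraries (8563 genes), the test recovered 10 of 50 genes changed 4-fold and 31 of 50 changed 16-fold, with 4 false calls among 68. With 22 libraries (7712 genes) it recovered 22 of 50 and 40 of 50, with 4 false calls among 107. For the wild type after contact against alone with 24 libraries (8697 genes), it recovered 5 of 50 changed 4-fold and 38 of 50 changed 16-fold, with 3 false calls among 66. A count of 0 in a group was compared with a floor of 3 counts over the summed totals of that group, which covers counting error only.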

Results

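Small RNAs were profiled in Trichoderma atroviride, a soil fungus that attacks other fungi, to ask how loss of dcr2 alters small RNA populations and their response to a prey fungus. Dicer enzymes such as the one named by dcr2 cut double-stranded RNA into small RNAs used in RNA interference. The wild type and the dcr2 mutant were each grown alone or facing Alternaria alternata, a plant pathogen, and mycelium was collected before contact, at contact and after contact. Each of the 8 groups held 3 libraries. Totals ranged from 754949 to 7787985 counts per library over 11863 gene IDs, of which 6191 were counted in every library and 1 in none. The mean log10 total was 6.499 in dcr2 and 6.38 in the wild type, a difference of 0.122 that an exact two-sided permutation test stratified over the 4 conditions did not separate from chance (p = 0.37, 160000 arrangements). Within single conditions the exact p was 0.2 growing alone, 1 before contact, 0.3 at contact and 0.2 after contact, where 3 libraries against 3 cannot go below 0.1.

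A single gene ID held much of the sequencing. Gene 298021 took between 3.81% and 69.2% of the counts of a library, and the 7 neighbouring IDs that include it took 10.8% to 86.8%. These 7 are neighbours in the order of the deposited IDs and were taken for their large mean shares, so they need not lie together in the genome. None of these 7 IDs matched the P1 annotation. In the wild type, gene 298021 held 30.0% ± 4.22 of counts growing alone, 36.7% ± 8.45 before contact, 34.5% ± 8.31 at contact and 14.7% ± 2.84 after contact (SD, n = 3 each). In dcr2 it held 50.5% ± 30.6, 17.5% ± 1.85, 44.95% ± 12.97 and 26.9% ± 20.9 in the same order. None of the 4 differences between strains at this gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.427, 0.318, 1 and 0.621), and the difference before contact passed without the 2 libraries described next (log2 fold change −2.56, adjusted p = 0.0327).

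The third library of dcr2 growing alone and the third of dcr2 after contact stood apart. Their profiles had a rank correlation of 0.934 with each other and of 0.449 to 0.55 with the other 22 libraries, which ranged from 0.753 to 0.984 among themselves (Spearman, across 11863 gene IDs, which are not independent). The 7 neighbouring IDs held 21.1% and 10.8% of their counts, against 34.1% or more in each of the other 22 libraries. Thinned to 754946 counts, they detected 11165 and 10986 gene IDs, and the others detected 6791 to 9484. Counts of changed genes are therefore given with all 24 libraries and, as an alternative added after the data were seen, with the 22 others.

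**Figure D1:**
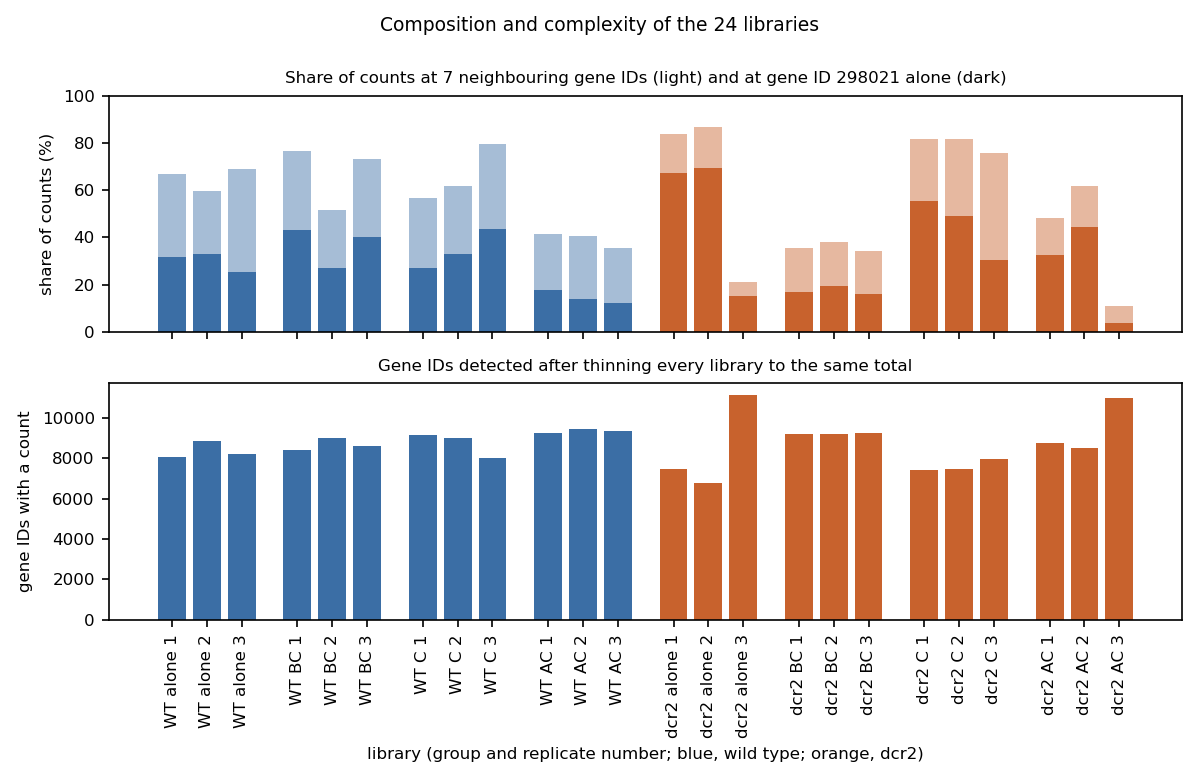
Composition of the 24 libraries by group and replicate number, with wild type in blue and dcr2 in orange. Upper bars give the percentage of counts at 7 neighbouring gene IDs (light) and at gene 298021 alone (dark), and lower bars the gene IDs with a count after thinning to 754946 counts. The third libraries of dcr2 alone and after contact detected 11165 and 10986 IDs, and the others at most 9484.

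**Figure D2:**
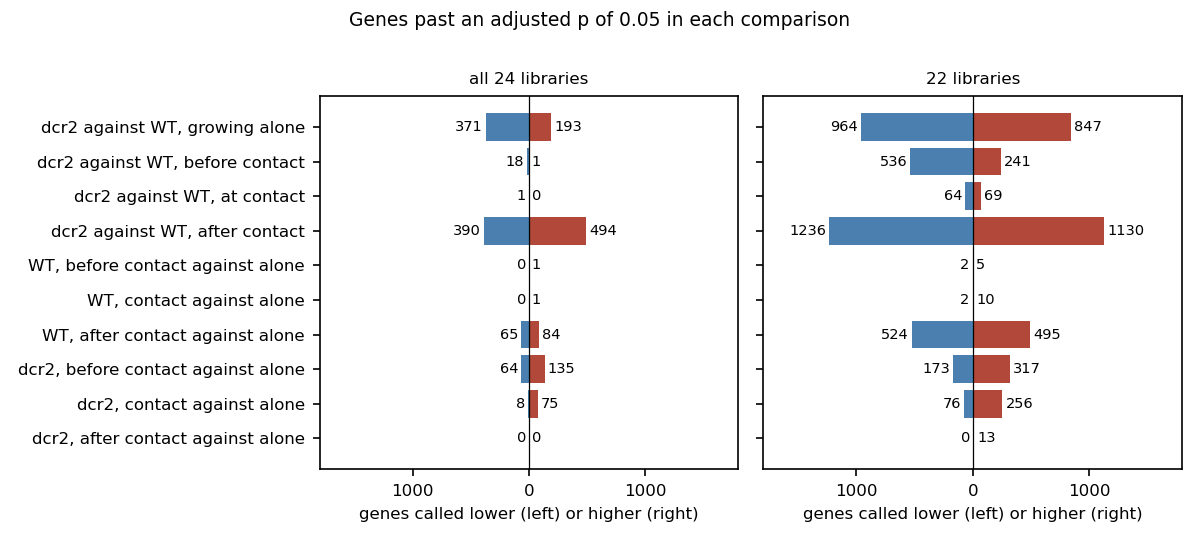
Genes past an adjusted p of 0.05 (edgeR quasi-likelihood test) in each comparison, with bars to the left for genes lower and to the right for genes higher in the first-named group. The left panel uses all 24 libraries and the right panel the 22 without the third libraries of dcr2 alone and after contact. After contact, dcr2 and the wild type differed at 884 genes with 24 libraries and at 2366 with 22.

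The first comparison asked how the strains differ without another fungus. Growing alone, small RNA counts were lower in dcr2 at 371 genes and higher at 193, with median log2 fold changes of −2.47 and 2.23. Gene 298113 (TrAtP1_009455) fell from 99.0 ± 15.9 CPM in the wild type to 6.02 ± 3.39 CPM in dcr2 (SD, n = 3 each). Gene 136201 (TrAtP1_003884) fell from 17.3 ± 1.70 to 2.85 ± 0.570 CPM. Gene 40670 (TrAtP1_012933) rose from 2.79 ± 1.01 to 21.3 ± 4.23 CPM. Gene 87581 (TrAtP1_009109) had no count in the 3 wild-type libraries and 55, 18 and 1513 counts in the dcr2 libraries, at least 233-fold higher over the summed libraries and at least 18-fold without the third dcr2 library. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change was −4.07 (SE 0.449, adjusted p = 0.000152) for gene 298113, −2.56 (SE 0.301, adjusted p = 0.000193) for gene 136201 and 2.77 (SE 0.424, adjusted p = 0.00109) for gene 40670. The adjusted p of gene 87581 was 0.00187. With 22 libraries 1811 genes passed (964 lower, 847 higher), of which 491 were among the 564. The count was 246 without the first and 274 without the third wild-type library, 1045 by DESeq2, and 0 in a fit to these 6 libraries alone. With library totals in place of TMM factors it was 168, 142 of them lower, and gene 136201 no longer passed.

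Among the genes called lower in dcr2 growing alone, the share of counts differed most at 3 gene IDs chosen after their values were seen, none of which matched the annotation. Growing alone, gene 297535 held 9.21% ± 2.12 of counts in the wild type and 0.00167% ± 0.00162 in dcr2 (SD, n = 3 each). Gene 300945 held 2.63% ± 0.385 and 0.00177% ± 0.000775, and gene 300960 held 1.78% ± 1.15 and 0.00461% ± 0.00594. All 3 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with log2 fold changes of −11.90 (SE 2.63, adjusted p = 0.0103), −10.18 (SE 1.94, adjusted p = 0.00416) and −8.30 (SE 1.55, adjusted p = 0.00386). After contact, gene 300960 fell again (log2 fold change −7.94, SE 1.53, adjusted p = 0.00392). Genes 297535 and 300945 had log2 fold changes of −5.12 and −4.61 there and did not pass (adjusted p = 0.0981 and 0.0579), and the third dcr2 library held 60140 and 18280 counts at them. Without that library both passed, at −11.83 (adjusted p = 0.00342) and −9.97 (adjusted p = 0.000737). Before contact the 3 log2 fold changes were −7.67, −6.84 and −4.78 and none passed (adjusted p = 0.124, 0.0676 and 0.105), while all 3 passed with 22 libraries (adjusted p = 0.00515, 0.000249 and 0.00268). At contact they were −1.13, −1.97 and −1.13, with no pass in either fit, and the dcr2 libraries spread from 73.9 to 31690 CPM at gene 297535. Gene 9789 lay the other way growing alone, at 0.00507% ± 0.00259 of counts in the wild type and 0.296% ± 0.450 in dcr2 (log2 fold change 4.88, SE 1.23, adjusted p = 0.0222). That call ended without any 1 of the wild-type libraries or without the third dcr2 library (adjusted p = 0.0655 to 0.116), which moved the log2 fold change to 3.41. With 22 libraries it passed, at 3.39 (adjusted p = 0.0241).

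**Figure D3:**
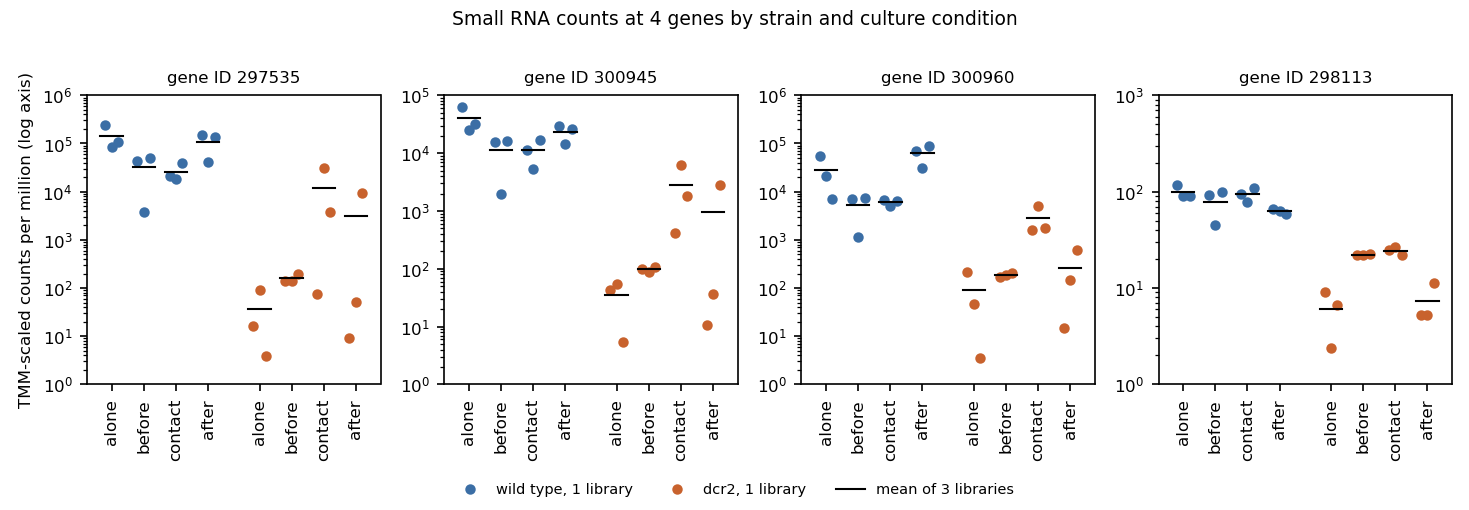
TMM-scaled CPM (log axis) at 4 gene IDs in each library, by strain and culture condition (alone, before contact, contact, after contact). Each point is 1 library and each line the mean of 3. Growing alone, the 3 wild-type libraries lie above the 3 dcr2 libraries at all 4 genes, and at contact the dcr2 libraries of gene 297535 spread from 73.9 to 31690 CPM.

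Before contact with A. alternata, 18 genes were lower and 1 higher in dcr2 than in the wild type. Gene 223880 (TrAtP1_009022) rose from 0.605 ± 0.234 CPM in the wild type to 13.7 ± 1.47 CPM in dcr2 (SD, n = 3 each). Gene 33108 (TrAtP1_002034) fell from 59.8 ± 40.2 to 3.35 ± 0.437 CPM. Gene 288238 (TrAtP1_007055) fell from 9.94 ± 6.68 to 0.163 ± 0.152 CPM, on 0, 3 and 1 counts in dcr2. The log2 fold changes were 4.41 (SE 0.663, adjusted p = 0.0164), −4.14 (SE 0.733, adjusted p = 0.0445) and −5.74 (SE 0.996, adjusted p = 0.0445) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With 22 libraries 777 genes passed (536 lower, 241 higher), the 19 among them. The count was 160 without the second wild-type library, 0 without the first or the third and 1 without any 1 of the dcr2 libraries, which ended the calls of genes 33108 and 288238, and that of gene 223880 was lost without the first or the third wild-type library. RLE size factors gave 1 higher and 2 lower, library totals 14 higher and none lower, DESeq2 321 and a fit to these 6 libraries alone 1277. The dcr2 libraries here were the replicates closest to counting noise (chi-square 1.46 to 1.79 per gene), so their small spread may be technical.

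At contact, a single gene differed between the strains with 24 libraries. Gene 51961 (TrAtP1_012558) fell from 18.1 ± 10.3 CPM in the wild type to 1.04 ± 0.146 CPM in dcr2 (SD, n = 3 each), on 1, 2 and 1 counts in dcr2. Its log2 fold change was −4.05 (SE 0.641, adjusted p = 0.0338) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Genes 223880 and 40670, higher in dcr2 before contact and growing alone respectively, had log2 fold changes of 3.05 (SE 0.630) and 1.80 (SE 0.372) at contact and did not pass (adjusted p = 0.213 for both). At an unadjusted p under 0.05 there were 582 genes. With 22 libraries 133 genes passed (64 lower, 69 higher), genes 51961, 223880 and 40670 included, and 58 passed when the second dcr2 library at contact was left out as well. The call of gene 51961 ended without the third wild-type library or any 1 of the dcr2 libraries, with RLE size factors, with limma-voom and in a fit to these 6 libraries alone. DESeq2 called 56 genes and library totals 93, all of the latter lower.

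After contact, the strains differed at 884 genes, 494 higher and 390 lower in dcr2, with median log2 fold changes of 2.66 and −2.23. Gene 219964 (TrAtP1_013099) fell from 281 ± 36.9 CPM in the wild type to 12.5 ± 3.09 CPM in dcr2 (SD, n = 3 each), and gene 223991 (TrAtP1_009099) from 453.0 ± 127 to 21.6 ± 2.25 CPM. Gene 254670 (TrAtP1_007854) rose from 16.2 ± 0.467 to 129 ± 44.8 CPM and gene 297834 (TrAtP1_000237) from 2.24 ± 0.947 to 116 ± 42.2 CPM. The log2 fold changes were −4.49 (SE 0.452) and −4.39 (SE 0.454), each with an adjusted p of 2.69e-05, 2.99 (SE 0.335, adjusted p = 4.79e-05) and 5.75 (SE 0.672, adjusted p = 7.76e-05) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With 22 libraries 2366 genes passed (1236 lower, 1130 higher), 720 of the 884 among them. The balance of directions was not stable, with 258 higher and 550 lower by limma-voom, 360 and 479 with the replicate number as a block, 426 and 639 without the third dcr2 library, and 622 and 248 without the first. The count was 277, 343 and 338 without the first, the second and the third wild-type library, 119 with library totals, and 0 in a fit to these 6 libraries alone, where these 4 genes had adjusted p of 0.0709 to 0.0901.

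The differences growing alone and after contact, which share no library, overlapped. Of the genes lower in dcr2, 154 were lower in both, against 16.1 for independent lists of the same sizes, and of those higher, 76 were higher in both, against 10.6. With 22 libraries the overlaps were 538 against 143 and 601 against 115, and 27 genes were lower and 44 higher in all 4 conditions. The 1236 genes called lower after contact in that fit had a median log2 fold change of −1.56 growing alone, −0.67 before contact and −0.52 at contact, and 91.2%, 81.6% and 77.1% of them were negative there. For the 1130 genes called higher the medians were 0.97, 0.47 and 0.45, with 93.2%, 90.2% and 86.5% positive.

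The next comparisons asked how small RNAs differed between each co-culture stage and growing alone within the wild type. Gene 129373 (TrAtP1_000250) was the only gene to change before contact and at contact with 24 libraries. It rose from 1.54 ± 1.89 CPM alone (0, 4 and 2 counts) to 67.7 ± 49.4 CPM before contact and 79.4 ± 12.2 CPM at contact (SD, n = 3 each). The log2 fold changes were 5.76 (SE 0.896, adjusted p = 0.0263) and 5.996 (SE 0.900, adjusted p = 0.0159) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, both against the same 3 control libraries. Before contact, genes 302027 and 152868 came next and did not pass (log2 fold changes 2.22, SE 0.500, and −1.59, SE 0.388, adjusted p = 1 for both). At contact, genes 233988 and 219964 did not pass (log2 fold changes 3.04, SE 0.573, and 2.06, SE 0.434, adjusted p = 0.161 and 0.295). With 22 libraries 7 genes passed before contact and 12 at contact, gene 129373 in both. Its call before contact ended with the replicate number as a block (adjusted p = 0.0566), with limma-voom, with library totals, in a fit to these 6 libraries alone, and without any 1 of the control libraries or the second library before contact. At contact it ended with limma-voom, with library totals, and without any 1 of the control libraries or the first or the third library at contact, and DESeq2 called 4 and 6 genes at the 2 stages.

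After contact, 84 genes were higher and 65 lower in the wild type than growing alone. Gene 219964 rose from 7.98 ± 5.86 to 281 ± 36.9 CPM and gene 292581 (TrAtP1_003200) from 6.12 ± 2.98 to 107 ± 4.70 CPM (SD, n = 3 each). Gene 128042 (TrAtP1_003518) fell from 40.2 ± 15.2 to 5.39 ± 1.65 CPM, and gene 163392 (TrAtP1_004652) from 65.0 ± 19.97 to 9.67 ± 3.44 CPM. The log2 fold changes were 5.08 (SE 0.479, adjusted p = 1.11e-05), 4.13 (SE 0.416, adjusted p = 1.71e-05), −2.86 (SE 0.367, adjusted p = 0.000274) and −2.73 (SE 0.364, adjusted p = 0.00041) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With 22 libraries, which keeps these 6, 1019 genes passed (495 higher, 524 lower), all 149 among them. Leaving out 1 of the 6 libraries left 27 to 61 genes, and DESeq2 called 363 and a fit to the 6 libraries alone 527. Library totals left 27 higher and 1 lower, with genes 128042 and 163392 not passing.

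Within dcr2, 135 genes were higher and 64 lower before contact than growing alone. Gene 265952 (TrAtP1_008931) rose from 16.6 ± 2.21 to 211 ± 19.3 CPM and gene 132064 (TrAtP1_012855) from 9.74 ± 4.15 to 101 ± 1.31 CPM (SD, n = 3 each). Gene 87581 fell from 72.1 ± 78.6 to 1.45 ± 0.490 CPM and gene 90691 (TrAtP1_010042) from 295 ± 206 to 60.8 ± 3.94 CPM. The log2 fold changes were 3.66 (SE 0.414) and 3.41 (SE 0.403), each with an adjusted p of 9.99e-05, −5.57 (SE 0.976, adjusted p = 0.00459) and −2.28 (SE 0.444, adjusted p = 0.00787) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With 22 libraries 490 genes passed (317 higher, 173 lower), 166 of the 199 among them. The fall of gene 87581 rested in part on the third control library, and its log2 fold change was −4.16 with 22 libraries (adjusted p = 0.00275). Most genes were lower in place of higher without the first control library (198 higher, 542 lower), without the second (294 higher, 1264 lower) and by DESeq2 (279 higher, 756 lower). The count was 740 and 1558 without these control libraries, 93, 99 and 97 without each library before contact (which ended the call of gene 90691), 0 in a fit to these 6 libraries alone, 300 by limma-voom and 1035 by DESeq2. With library totals 3080 genes were higher and 254 lower, and gene 90691 did not pass. The small SDs before contact may be technical, since those libraries were the replicates closest to counting noise (chi-square 1.46 to 1.79 per gene).

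At contact, 75 genes were higher and 8 lower in dcr2 than growing alone. Gene 299629 (TrAtP1_002831) rose from 15.1 ± 8.28 to 674 ± 291 CPM and gene 298187 (TrAtP1_000649) from 16.99 ± 11.8 to 726 ± 517 CPM (SD, n = 3 each). Gene 39090 (TrAtP1_002866) fell from 11.6 ± 8.42 to 1.58 ± 0.574 CPM and gene 45281 (TrAtP1_007492) from 61.4 ± 21.1 to 22.3 ± 5.98 CPM. The log2 fold changes were 5.47 (SE 0.703) and 5.40 (SE 0.739), each with an adjusted p of 0.0013, −2.88 (SE 0.567, adjusted p = 0.0136) and −1.48 (SE 0.316, adjusted p = 0.0261) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With 22 libraries 332 genes passed (256 higher, 76 lower), 80 of the 83 among them. The count was 44 and 34 without the second and the third library at contact, 407 by DESeq2, and 0 with library totals or in a fit to these 6 libraries alone. The calls of genes 39090 and 45281 ended without the third control library or without the first or second library at contact, and that of gene 39090 also without the third and with limma-voom. Without the third control library their log2 fold changes were −2.06 and −1.16. With 22 libraries, which also lack it, they were −2.04 and −1.15 and passed (adjusted p = 0.0332 and 0.0115).

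After contact, no gene passed in dcr2 against growing alone with 24 libraries. Genes 221642 and 90908 had log2 fold changes of 1.46 (SE 0.292) and 4.46 (SE 0.916) and gene 87581 of −4.81 (SE 0.942), with an adjusted p of 0.287 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 205 of 8980 genes, fewer than chance alone would give at that threshold. limma-voom called 0 genes and DESeq2 18. With 22 libraries 13 genes were higher and 0 lower, genes 221642 (adjusted p = 0.0376) and 90908 (adjusted p = 0.000367) among them. Without the third library after contact alone 10 genes passed, without the third control library 4, and without the second control library 1.

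The last comparison asked whether the response to A. alternata differed between the strains. In the joint test over the 3 stages, small RNA counts at 38 genes differed between the strains in their change from growing alone. The same controls of a strain served all 3 stages, so culture age cannot be told apart from co-culture here. Genes 219964 and 223991 rose after contact in the wild type, by log2 fold changes of 5.08 and 4.40, where in dcr2 the values were −0.59 and −0.10. The difference of responses at that stage was −5.68 (SE 0.614) and −4.50 (SE 0.596). Gene 300770 (TrAtP1_002295) was at 46.9 ± 20.4 CPM in the wild type and 0.539 ± 0.320 CPM in dcr2 growing alone, and at 16.4 ± 1.84 and 32.6 ± 2.53 CPM before contact (SD, n = 3 each). Its responses differed by 7.71 (SE 0.999) before contact and 6.63 (SE 0.997) at contact, and those of gene 140865 (TrAtP1_006537) by 3.06 (SE 0.455) before contact. The joint adjusted p was 0.00121, 0.00156, 0.00134 and 0.00628 for genes 219964, 223991, 300770 and 140865 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

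By stage, 15 genes differed in response before contact (14 with a higher response in dcr2), 3 at contact (all higher) and 7 after contact (3 higher, 4 lower). The 84 genes called higher after contact in the wild type had a median log2 fold change of 2.55 there and 0.36 in dcr2, where 62 were positive. The 65 called lower had medians of −2.24 and −0.14, and 35 were negative in dcr2. With 22 libraries the 495 called higher had medians of 1.56 and 0.32, with 354 positive in dcr2 and 12 of its 13 calls among them, and the 524 called lower had medians of −1.57 and −0.24, with 368 negative in dcr2. Both sets were selected on the wild-type libraries, so their wild-type median lies further from 0 than their own repeat would. With 22 libraries 491 genes passed the joint test, the 38 among them, and 149, 85 and 45 passed at the 3 stages. The joint count was 210 by DESeq2 and 1 with library totals, where of these 4 genes only gene 300770 passed. It was 82 without the third dcr2 library after contact and between 15 and 23 without 1 of the first or the third libraries of the wild type or dcr2 before contact, of the 3 wild-type libraries after contact, of the first wild-type or second dcr2 library at contact, or of the first dcr2 library after contact. Without the second wild-type library at contact it was 25.

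**Figure D4:**
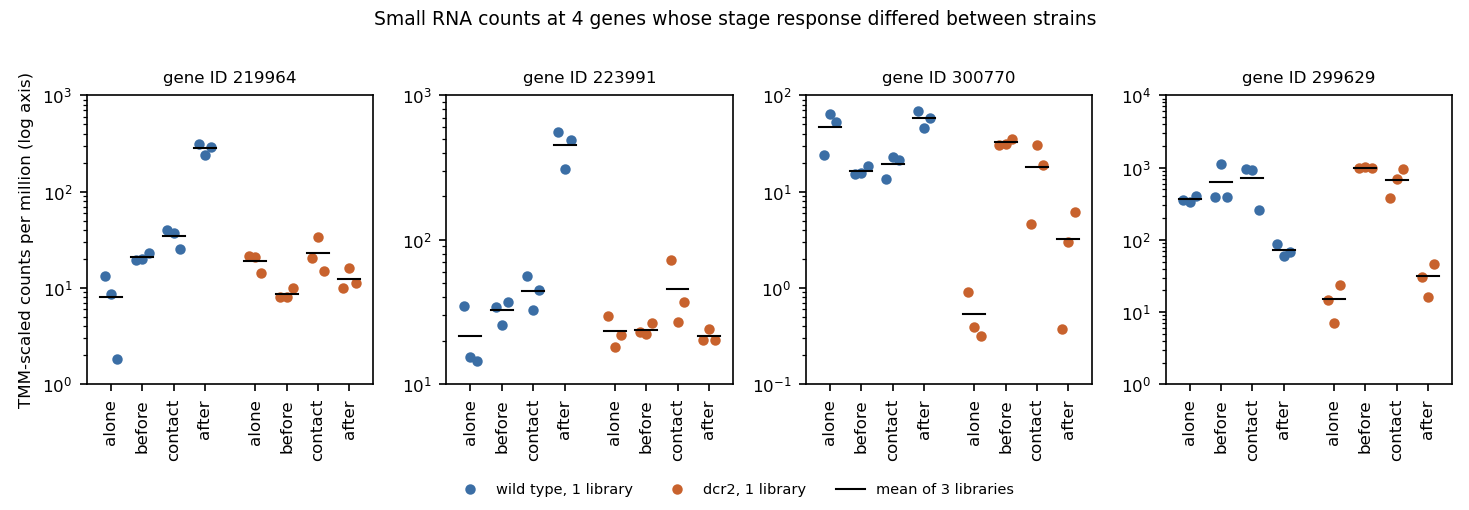
TMM-scaled CPM (log axis) at 4 gene IDs whose change from growing alone differed between strains, by strain and culture condition (alone, before contact, contact, after contact). Each point is 1 library and each line the mean of 3. Genes 219964 and 223991 reach means of 281 and 453.0 CPM after contact in the wild type and 12.5 and 21.6 CPM in dcr2.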

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

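The joint test and the count of splits were planned, and no test in this part was chosen after its result was seen. A difference in response between the strains, tested as an interaction by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, brought 38 genes to attention. Of 100 splits that exchanged strain labels within conditions, 2 gave as many genes, the real one included, and the highest other split gave 70. These splits do not decide whether chance is excluded, because exchanging strain labels carries the strain difference shared by all conditions into the other splits. There it can widen the spread, which lowers a count. Where labels are exchanged more in some conditions than in others, it can also enter the interaction, which raises a count.

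Among the named genes, those with a response higher after contact in the wild type were 219964 (joint adjusted p = 0.00121), 223991 (0.00156) and 292581 (0.00383). Genes 128042 (0.00928) and 163392 (0.0104) fell after contact in the wild type. Genes 300770 (0.00134), 140865 (0.00628) and 136201 (0.0073) were lower in dcr2 than in the wild type growing alone by their mean CPM. Genes 299629 (0.0199), 298187 (0.0354) and 45281 (0.0337) were called at contact in dcr2. Genes 254670 (0.0354) and 297834 (0.0404) were higher in dcr2 after contact.

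Each pairwise count comes from 3 libraries against 3, which make 10 splits, too few for a share under 0.05. In 9 of the 10 comparisons the real split was the 1 split to reach its count. The real counts were 564, 19, 1 and 884 for dcr2 against wild type growing alone, before contact, at contact and after contact, 1, 1 and 149 for the 3 stages in the wild type, and 199 and 83 before contact and at contact in dcr2. The highest other split gave 0 in each except dcr2 at contact against alone, where it gave 2. Every other split mixes the 2 groups, so a true difference would widen its spread and hold its count down. These low counts therefore add no support.

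For dcr2 after contact against alone, all 10 splits gave at least the real count of 0. The 4 splits that placed the third library of each group together gave 2797 to 4649 genes, and the other splits gave 0. This points to a structure of the samples other than the culture condition. The real split parts all 3 same-numbered pairs, the other 3 splits that part all 3 pairs gave 0, and the 4 large ones part 1 pair.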

How the results depend on the processing

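The fits to 22 and 21 libraries were chosen after the data were seen, and the other settings before. Counts below are genes past an adjusted p of 0.05, and where no cause is named the cause was not tested. Main counts were 564, 19, 1 and 884 for dcr2 against wild type growing alone, before contact, at contact and after contact. They were 1, 1 and 149 for the wild type before contact, at contact and after contact against alone, 199, 83 and 0 for dcr2 at the same stages, and 38 for the strain by stage interaction. The log10 difference in library totals was 0.0683 to 0.171 with each library left out.

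RLE size factors gave 3 for dcr2 against wild type before contact and 0 at contact. Library totals without TMM factors gave 168 growing alone, 93 at contact and 119 after contact for dcr2 against wild type. For the wild type they gave 0 before contact, 0 at contact and 28 after contact, for dcr2 3334 before contact and 0 at contact, and for the interaction 1. That scaling moved the median log2 fold change of all genes, in dcr2 against wild type, from 0.00 to 1.11 before contact and from −0.01 to −1.13 at contact, and in dcr2 before contact against alone from −0.26 to 1.21, so the directions of calls there follow the scaling. RLE moved the last of these to −0.44. Without a filter the count before contact for dcr2 against wild type was 5, and with the stricter filter 82.

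limma-voom gave 0 for dcr2 against wild type at contact, 0 for the wild type before contact and 0 at contact, and 300 for dcr2 before contact. DESeq2 gave 1045 growing alone, 321 before contact and 56 at contact for dcr2 against wild type. It gave 4, 6 and 363 for the 3 stages in the wild type, 1035, 407 and 18 for those in dcr2, and 210 for the interaction. Fits to the compared groups alone estimated the spread from 6 libraries. They gave 0 growing alone, 1277 before contact, 0 at contact and 0 after contact for dcr2 against wild type, 0 before contact and 527 after contact for the wild type, and 0 before contact and 0 at contact for dcr2. The 1277 before contact rest in part on the small spread of the dcr2 libraries (chi-square 1.46 to 1.79 per gene), which may be technical. No such fit was made for the interaction, which uses all groups.

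The replicate number as a block gave 0 in place of 1 for the wild type before contact, where every library correlated best with its own number. It gave 0 for dcr2 after contact, where the profile shared by the third libraries keeps the correlations from showing a pairing. Elsewhere the libraries shared only a number. There the block gave 87 for dcr2 against wild type before contact and stayed within 1.5 times the main count in the other comparisons. In no comparison but the wild type before contact did every library correlate best with its own number.

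With 22 libraries the counts were 1811, 777, 133 and 2366 for dcr2 against wild type in the order above, 7, 12 and 1019 for the wild type, 490, 332 and 13 for dcr2 and 491 for the interaction. The common biological coefficient of variation fell from 0.591 to 0.298 in that fit. With 22 libraries and limma-voom they were 1486, 989, 154 and 2542, then 0, 21 and 947, then 515, 215 and 6, and 315. With 21 libraries the contact comparison gave 58.

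With each library left out in turn, dcr2 against wild type ranged from 246 to 598 growing alone, 0 to 160 before contact, 0 to 1 at contact and 277 to 1065 after contact. The wild type ranged from 0 to 1 before contact, 0 to 1 at contact and 27 to 61 after contact. For dcr2 the ranges were 93 to 1558, 34 to 99 and 0 to 10, and for the interaction 15 to 82. Where 1 library remained out, the other 2 stood for their group. Among the named genes, the direction reversed in 1 case, gene 298021 in dcr2 against wild type after contact without the second dcr2 library after contact (log2 fold changes with a library left out −0.0677 to 1.27), a difference that passed in neither fit. Calls of named genes were lost in 39 of the cases with a library left out, 21 with the compared groups alone, 15 with library totals, 5 with limma-voom, 2 with RLE, 2 with 22 libraries and limma-voom and 1 with the block. Depth limits genes with few counts: genes 288238 and 51961 rest on 0 to 3 counts per dcr2 library in the comparisons that named them.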

Other observations

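The contrasts of gene 129373 and the counts of genes called in dcr2 after contact against alone, both with 24 libraries, were planned. The other tests in this part were chosen after the results they measure were seen. With 22 libraries, where 2 libraries remain in both dcr2 groups, a small set of genes was called higher after contact in both strains. With 24 libraries edgeR called 0 genes in dcr2 at this stage (DESeq2 18, limma-voom 0) and none was shared. At an unadjusted p under 0.05 there were 205, fewer than chance alone would give among the 8980 tested. In the fit to 22 libraries, 495 genes were higher in the wild type and 13 in dcr2 after contact than growing alone, and 12 were shared, against 0.77 for independent lists of these sizes. The strains share no library, but 1 estimate of each gene's spread served both, so the number for independent lists is a low yardstick. Gene 90908, 1 of the 12, was at 75.2 and 58.2 CPM in the dcr2 libraries kept after contact and at 1.55 CPM in the library left out. Gene 53468 (chosen after its values were seen) rose from 33.2 to 874 CPM in the wild type and from 35.4 to 872 CPM in dcr2, with log2 fold changes of 4.71 and 4.56 (adjusted p = 6.39e-06 and 0.000687, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Gene 298114, likewise, rose from 35.5 to 253 CPM and from 40.5 to 256 CPM, with log2 fold changes of 2.78 and 2.64 (adjusted p = 5.9e-06 and 0.000687). Gene 129373 was the gene that responded at each stage in the wild type with 24 libraries, with log2 fold changes of 5.76, 5.996 and 4.82. In dcr2 they were 5.76 (adjusted p = 0.00046), 5.89 (adjusted p = 0.0013) and 3.43 (adjusted p = 0.386), all 3 of a strain against the same controls. The table does not separate reads of the 2 fungi, so the fungus that made these small RNAs is open.

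Genes whose small RNAs were lower in dcr2 growing alone and after contact gathered at the ends of chromosomes in the P1 gene order. Growing alone with 24 libraries, 14 of the 326 lower genes with a place in that order lay within 20 genes of 1 of the 14 ends, 4.29% against 1.89% of the tested genes. Chance placement is argued against as the whole account by rotations of the calls along the order, which keep their clustering (share with as many 0.0173). Draws matched on abundance gave 3.71 on average and at most 13 (share with as many 1e-04, the smallest the draws can give). They take genes singly, while the lower genes clustered, with 45 adjacent pairs in the order of the deposited IDs against a random mean of 12.4. That share therefore overstates the evidence against abundance. No test kept both clustering and abundance, and the 20-gene window was set after the data were seen. After contact it was 26 of 345 (rotations 0.00142), and with 22 libraries 88 of 895 growing alone and 104 of 1132 after contact. Before contact it was 1 of 15 with 24 libraries (rotations 0.247) and 81 of 463 with 22 (rotations 0.000127), and at contact 1 of 57 with 22 (1.75% against 1.79% of the tested genes, rotations 0.642). Of the tested genes within 5 of an end, 39 of 47 were lower both alone and after contact with 22 libraries (83%), against 62.8% from 6 to 10, 29.4% from 11 to 20 and 5.06% beyond 100, and all 14 ends held a gene lower in dcr2 growing alone (8 with 24 libraries). That small RNAs from genes near chromosome ends depend on dcr2 is a candidate explanation. Reads shared between similar genes stay open, since counts that were not whole occurred at 0 of the 88 lower genes near an end and at 6 of the 807 with a place elsewhere, too few to decide, and the authors' handling of reads with several places is not given. Of the genes called in the wild type after contact with 24 libraries, 0 of the 65 lower and 0 of the 80 higher with a place lay there. Rotations gave means of only 1.23 and 1.51, so these lists are too short to show a lack of enrichment. With 22 libraries it was 0 of 504 lower and 7 of 471 higher, with rotation means of 9.02 and 8.43, and no enrichment was seen.

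The third libraries of dcr2 growing alone and after contact shared a profile unlike the other 22. Sequencing depth is argued against, since thinned to the same total they detected at least 10986 gene IDs and the others at most 9484. The dcr2 mutation or the culture stage is argued against as well, since their rank correlation with the other libraries of their own groups was at most 0.504. A wild-type library under a dcr2 label is argued against as the account of this profile, since the highest rank correlation with a wild-type library was 0.521 growing alone and 0.55 after contact, and wild-type libraries reached at least 0.788 among themselves. Whether the 2 libraries hold wild-type RNA is not settled by the levels of genes lower in dcr2. Over 61 such genes, chosen with the 22 other libraries, their medians were 43.3% (quartiles 12.2 to 107) and 57.8% of the wild-type level growing alone, against 0.229% to 2.44% in the other libraries of both groups, while genes 297535, 300945 and 300960 reached at most 0.0333% of their wild-type share growing alone and at most 12.7% after contact. The 61 genes were chosen for low levels in those other libraries, so that contrast is fixed by the choice and is no evidence of wild-type RNA. Another RNA population, such as fragments of long transcripts, may underlie the shared profile (rank correlation 0.934 between both libraries), but it cannot be told apart from other sources without read lengths.

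At contact, the second dcr2 library held more small RNAs than the other 2 at genes far lower in dcr2 in the fit to 22 libraries. Over 61 genes with a log2 fold change under −4 both alone and after contact (22 libraries), it reached a median of 9.78% of the wild-type level growing alone, against 2.3% and 5.62% in the first and the third and 3.66% to 6.89% before contact. The third libraries growing alone and after contact, which that fit leaves out, lay far above it at 43.3% and 57.8%. The wild-type libraries at contact were themselves at 51%, 38.3% and 26.9% of the wild-type level growing alone. Counting noise in a shallow library is argued against, since the total of the second dcr2 library was 1.79 times that of the first. Carry-over of wild-type RNA is a candidate explanation: 70.5% of the genes lay within 2-fold of the same percentage. The dcr2 libraries before contact, the other 2 at contact and the 2 left out of the fit had 29.5% to 47.5%. The dcr2 libraries that served to choose the genes had 9.84% to 41%, where the choice itself favours counts near 0 and so a low share. Low counts also weigh on the first library at contact, whose lower quartile was 0. Small RNAs regained in dcr2 at contact cannot be told apart from carry-over. The second library exceeded the third, the higher of the others, only 1.74 times, and their quartiles overlapped (5.98% to 14.2% and 2.62% to 13.3%). The quartiles of the first library, 0% to 5.96%, lay below those of the second.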
